A study of Mus musculus with 3 samples.

How the data were processed

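Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against MafG on mouse embryonic fibroblasts that lack the MafF, MafG and MafK genes and carry a tethered Nrf2-MafG construct, per the labels. MafF, MafG and MafK are the small Maf proteins, the DNA-binding partners that Nrf2 needs to bind DNA. The series holds 3 libraries. One is from cells given vehicle, 1 is from cells given 100 µM diethyl maleate (DEM) for 4 hours, and 1 is the input DNA of these cells. The chromatin was fixed with formaldehyde, and ChIP and input libraries were prepared with a NEBNext kit, per the labels' protocols. Summit lists were used for the vehicle and the DEM library, and no list of the input library was used here.

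The submitters' processing notes name bcl2fastq 2.16.0.10, Bowtie2 2.2.9, MACS2 2.1.1.20160309 and the mouse build mm9. The deposited lists are in the layout of MACS2 summit files, with 5 columns and no header. Each line is 1 summit, the base of highest signal in a called peak, with its chromosome, position and score. The score that the authors deposited is a −log10 value of a p or q value, and which of these is not given in the sources used here. The lowest scores were 1.71 in the vehicle list and 1.73 in the DEM list. The calling threshold, the treatment of duplicate reads and the use of the input library as a control are not given in the sources used here. Peaks were numbered separately in each list, and 0 of 180 matched summits stood at the identical base in both. Scores are each peak's own value as the authors' peak caller gave it. They depend on sequencing depth, so they were used to describe, rank and filter summits within a list and to order the shared sites in each list. The alternatives that apply 1 score minimum to both lists do not put the lists on a common scale.

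Positions are given 1-based in mm9. A summit was called matched when a summit of the other list lay within 100 bp. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error over summits only. The matching was tested on simulated lists of 182 positions with 0, 60 or 150 planted matches to the 1246 DEM summits, and it recovered 0, 60 and 150. The other simulated positions were kept over 1 kb from any DEM summit, so this checked the code and not the choice of distance. The expected overlap was taken from 1000 sets of random positions on the same chromosomes, each drawn between base 1 and the last summit of either list. These positions ignore gene density, chromatin state and mappability. Summits within 500 bp were joined into regions. Permutation tests in the closing section used 100000 resamples. The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

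Each condition had 1 library, so no test between vehicle and DEM was made and no difference between them has a replicate check. The read depth of the libraries is unknown. The named sites follow a rule fixed before the data were examined: the 10 highest-scoring summits of each list, the 10 highest-scoring DEM summits without a vehicle match, and up to 10 vehicle summits without a DEM match. The alternatives were other match distances, score minimums of 10 and 20, a DEM list shortened to the length of the vehicle list, other distances for joining summits, and a restriction to chromosomes 1 to 19, X and Y. These were fixed at the same time, except the match and joining distances of 1 kb and the removal of runs of close summits (at least 4 summits with gaps under 1 kb). Assigning summits to genes, counting binding motifs and comparing 13 fixed gene lists were also planned. They need gene coordinates and sequence in mm9, which were not used here, since the gene table at hand was in GRCm38 coordinates. Sites are therefore named by chromosome and position.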

Results

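ChIP-seq with an antibody against MafG was used to map the tethered Nrf2-MafG heterodimer in small Maf-deficient mouse embryonic fibroblasts with and without DEM. Nrf2 is a transcription factor of the oxidative stress response that binds DNA as a heterodimer with a small Maf protein. DEM is an electrophile that depletes glutathione and activates Nrf2. The labels give the MafG gene as deleted in these cells, which leaves MafG sequence in the tethered protein as the target of the antibody. The series holds no library from cells without the construct, and motifs were not counted, so signal unrelated to the construct was not assessed. The data were 1 summit list from vehicle-treated cells and 1 from cells treated with 100 µM DEM for 4 hours. The read depth behind the lists is unknown, and no value below has a replicate error.

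The first comparison asked how many sites were called in each condition. The vehicle list held 182 summits and the DEM list 1246, which was 6.85 times as many. Both lists covered the same 20 chromosomes, 1 to 19 and X, with 0 summits on other contigs. The median score was 10.6 in the vehicle list, with quartiles of 6.64 and 17.9. It was 15.2 in the DEM list, with quartiles of 8.87 and 32.7. Scores depend on depth, so these levels describe each list and do not measure a difference in binding. With 1 library per condition, the difference in number was not tested.

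**Figure D1:**
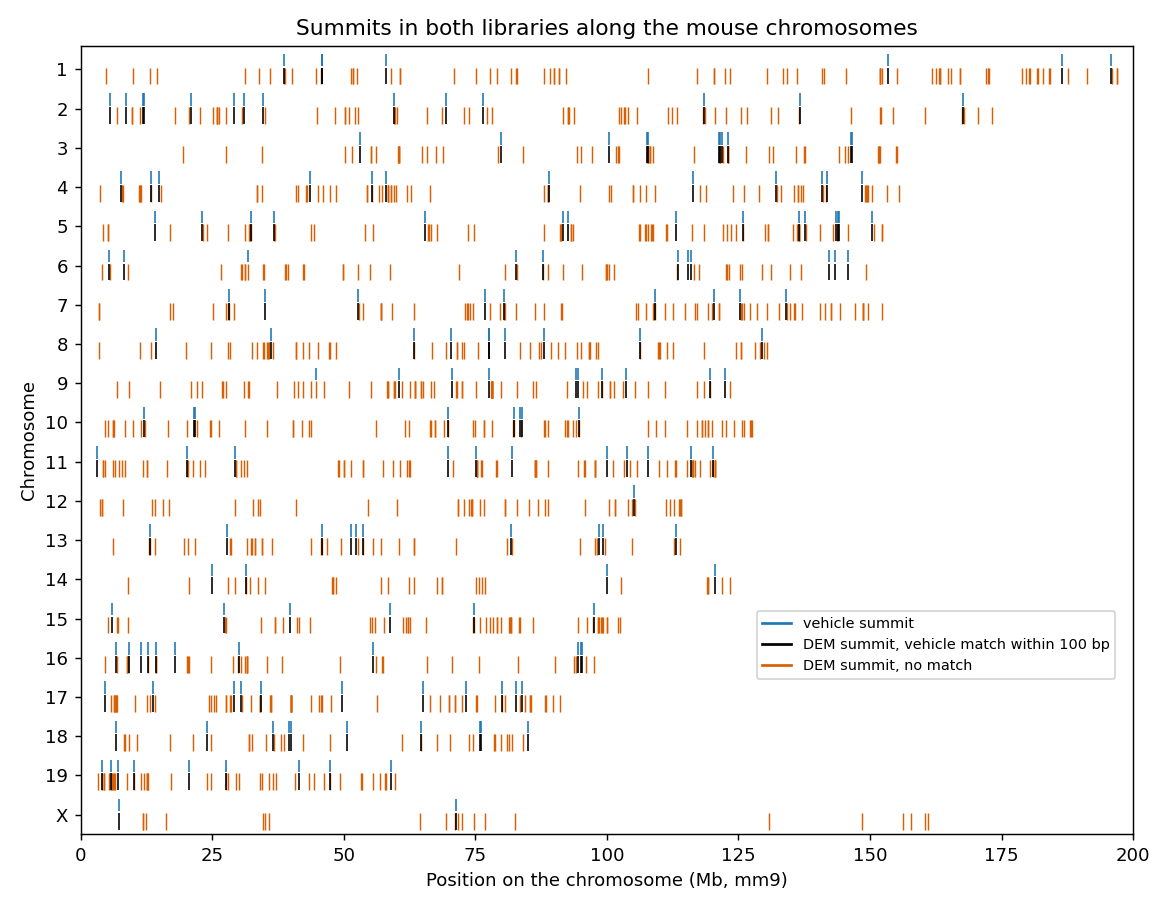
Positions of all summits along the mouse chromosomes (x axis, Mb in mm9; y axis, chromosome), with the 182 vehicle summits in blue above each chromosome line, and below it the 180 DEM summits with a vehicle summit within 100 bp in black and the 1066 DEM summits without one in orange. The black marks sit under 180 of the 182 blue marks, and the orange marks spread over all 20 chromosomes.

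The second comparison asked whether the sites called with vehicle were also called with DEM. Of the 182 vehicle summits, 180 had a DEM summit within 100 bp, a share of 98.9% (95% interval 96.1 to 99.9%). Random positions on the same chromosomes gave a mean of 0.02 matches per set and at most 1. Conversely, 1066 of the 1246 DEM summits had no vehicle summit within 100 bp, and the 180 that had one made up 14.4% of the DEM list (95% interval 12.5 to 16.5%). The summits of a matched pair stood a median of 17.5 bp apart, with quartiles of 6 and 34.25 bp. Of these pairs, 163 stood within 50 bp. The DEM summit lay at the higher coordinate in 88 pairs and at the lower coordinate in 92.

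The strongest sites were largely shared. The highest-scoring site in both lists lay on chromosome 8, at position 77613636 in the vehicle list (score 131.2) and 77613645 in the DEM list (score 378.4). The third-ranked site of both lists lay 5771 bp away in the DEM list, at position 77607874 (score 303.9), and at 77607890 in the vehicle list (score 91.9). These were the only vehicle summits less than 10 kb apart. Sites on chromosome 11 at 75197198, chromosome 4 at 14826091 and chromosome 2 at 76546779 also stood among the 10 highest of both lists, with DEM scores of 310.7, 250.3 and 250.2. In all, 5 sites belonged to both sets of 10.

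The other members of the vehicle set of 10 were all matched and ranked between 11 and 41 in the DEM list. They lay on chromosome 5 at 125870649 (score 102.5, DEM rank 18), chromosome 2 at 167590855 (91.7, rank 12), chromosome 19 at 10053094 (72.2, rank 11), chromosome 6 at 5380171 (53.9, rank 15) and chromosome 4 at 13348778 (49.8, rank 41). The other members of the DEM set of 10 were also matched. They lay on chromosome 3 at 107626355 (score 292.4, vehicle rank 14), chromosome 17 at 82776775 (257.6, rank 64), chromosome 13 at 45846793 (231.1, rank 25), chromosome 15 at 97617310 (230.03, rank 15) and chromosome 9 at 122380885 (226.7, rank 13). Ranks in lists of different length do not measure a change in binding.

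The third comparison asked where the shared sites stood in the DEM list. The median shared summit lay 8.35% from the top of the DEM scores, and the median unmatched one 56.5% from the top. Of the 100 highest-scoring DEM summits, 88 had a vehicle match (95% interval 79.98 to 93.6%). In the top decile of the DEM list the matched share was 86.4% (95% interval 79.1 to 91.9%), and in the second decile it was 40.8% (95% interval 32.1 to 49.9%). It was 11.3% in the third decile (95% interval 6.31 to 18.2%), an interval that does not overlap that of the second. Below the median DEM score, 1 of 616 summits had a vehicle match (0.162%, 95% interval 0.00411 to 0.901%). When the DEM list was shortened to its 182 highest-scoring summits, 136 of them were matched.

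**Figure D2:**
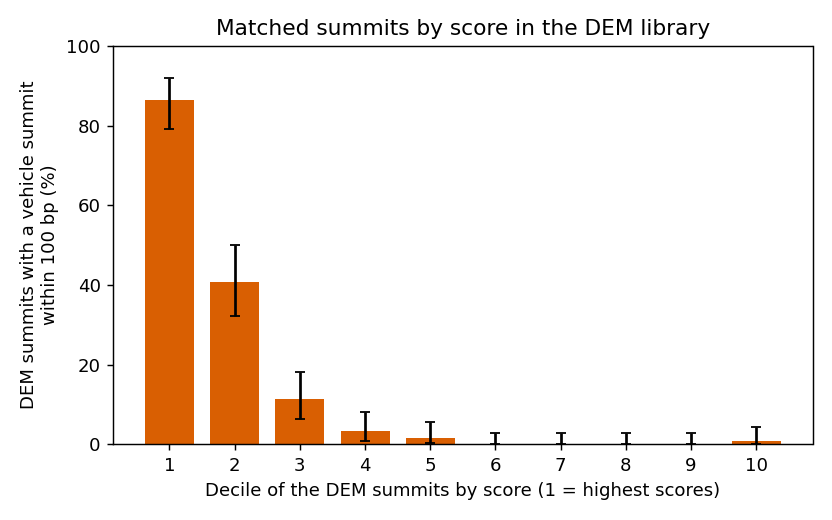
Share of DEM summits with a vehicle summit within 100 bp (y axis, %) for each decile of the DEM list ordered by score (x axis, 1 for the highest scores), with bars for the share and whiskers for the exact 95% interval over summits. The share falls from 86.4% in the first decile to 11.3% in the third, and to 0% in deciles 6 to 9.

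Some DEM summits with high scores had no vehicle counterpart. Of the 104 DEM summits that scored at or above the median of the shared ones (82.4), 14 were unmatched. The highest lay on chromosome 6 at 31767832 (score 220.3), where the nearest vehicle summit, at 31767482 (score 35.9), stood 350 bp away and so fell outside the match distance. The next was on chromosome 13 at 12906338 (score 173.1), which ranked 29 in the DEM list and stood 212 kb from the nearest vehicle summit. Sites on chromosome 11 at 48937845 (score 110.2), chromosome 9 at 42269588 (101.9), chromosome 12 at 34054590 (93.3) and chromosome 10 at 69864951 (93.0) followed. The 10 highest-scoring of the 14 also included sites on chromosome 4 at 106286350 (90.2), chromosome 5 at 142997589 (89.9), chromosome 15 at 77712380 (89.5) and chromosome 3 at 154898621 (87.0). An uncalled site in the vehicle list is one that did not reach the authors' threshold at an unknown depth, not one shown to be unbound.

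Vehicle summits without a DEM match numbered 2, and both had a DEM summit nearby. One was the chromosome 6 site above. The other, on chromosome 9 at 44669316, had the lowest score of the vehicle list (1.71) and stood 101 bp from a DEM summit at 44669417. Within 500 bp, all 182 vehicle summits had a DEM summit, so 0 vehicle sites were without one. With no replicate library this is a description of these lists.

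The order of scores was compared across the 180 shared sites, which gave lists of equal length. The order was similar, with Spearman's rho of 0.71 across sites, which are not independent replicates. Of the 20 highest-scoring shared sites in each library, 15 were in both sets. The site on chromosome 17 at 82776775 ranked 5 by DEM score and 63 by vehicle score, and the chromosome 8 site at 77613645 ranked 1 by both.

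**Figure D3:**
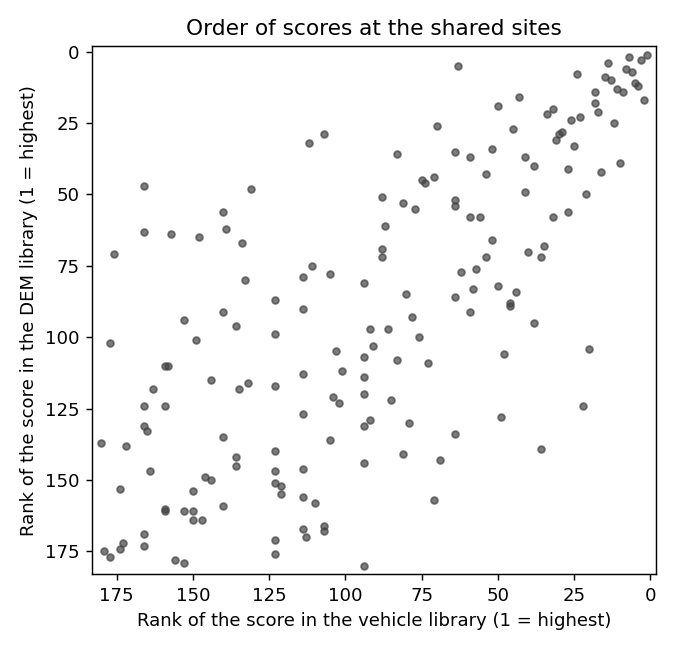
Rank of each of the 180 shared sites by its score in the vehicle library (x axis) and in the DEM library (y axis), 1 being the highest score in that library, with 1 point per site. The points run from the lower left to the upper right (Spearman's rho 0.71 across sites), with 15 sites among the 20 highest of both.

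Summits were then examined for grouping along the genome. Joining summits within 500 bp left 182 vehicle regions and 1244 DEM regions, so nearly every summit was a region of its own. The DEM list held 42 neighbouring pairs of summits no more than 10 kb apart, against a mean of 6.50 and at most 19 in 1000 sets of random positions. One run of 5 low-scoring summits on chromosome 17, between 39980487 and 39982760, took part in 5 of these pairs, and 37 pairs were left without it. In 34 of the 42 pairs neither summit was matched, in 7 pairs 1 was, and in 1 pair, on chromosome 8, both were. Without the run, neither summit was matched in 29 pairs. In the whole DEM list 1066 of 1246 summits were unmatched, so most pairs would have neither summit matched in any case. Whether close pairs differ from the rest of the list was not tested. Besides the chromosome 8 pair, the pair with the highest scores lay on chromosome 16 at 14351036 and 14352894 (scores 70.1 and 159.3), where only the second position had a vehicle match. The vehicle list held 1 such pair, against a random mean of 0.131 and at most 2.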

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

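Of 31 alternative values computed for these results, 6 came from settings that had nothing to remove or join: keeping chromosomes 1 to 19, X and Y in both lists, and joining or removing close summits in the vehicle list. Of the other 25 values, 19 lay within 1.5 times the reported one. A score of at least 10 left 92 vehicle summits, and a score of at least 20 left 40 vehicle and 491 DEM summits, which moved the ratio of the lists from 6.85 to 9.17 and 12.3. The lists shrink under a higher minimum by construction, and as scores depend on depth, a common minimum is no check of the ratio. With a score of at least 10 in both lists, 91 vehicle summits kept a match, out of 92. Against the 182 highest-scoring DEM summits, 136 vehicle summits were matched and 46 of those DEM summits were not, since the shortened list leaves fewer to count. Match distances of 50 to 500 bp gave 163 to 182 matched vehicle summits. The match and joining distances of 1 kb, and the removal of a run of 5 close DEM summits (1241 summits and 37 neighbouring pairs left), were chosen after seeing the data and moved no value by over 1.5 times. No paired analysis was possible because each condition has 1 library, and for the same reason no replicate could be left out. The alternative settings for gene position, motifs and gene lists were not run, since sequence and annotation in mm9 were not used here. The unknown read depth limits every count, as a weaker or shallower library yields fewer calls.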

Other observations

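The random sets were planned beforehand, but the prediction for them was written after the matches had been seen. Tests of pooled calling, of score order and of chromosomes were chosen after the matches and the summits per chromosome had been seen. The test of summit distance was chosen before its result was seen.

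Individual shared sites departed from the common order of scores, as values picked after they were seen. The site on chromosome 17 at 4626366 ranked 1193 of 1246 in the DEM list (score 4.35), although its vehicle counterpart at 4626324 ranked 95 of 182 (score 9.55). It was the only shared site below the median of the DEM scores. Among the 180 shared sites, those on chromosome 9 at 94440892 and chromosome 16 at 11456586 ranked 22 and 20 by vehicle score but 124 and 104 by DEM score. In the other direction, the sites on chromosome 18 at 50658596 and chromosome 5 at 36722796 ranked 47 and 71 by DEM score but 166 and 176 by vehicle score. Without a replicate, the spread of such ranks between libraries of 1 condition is unknown.

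The DEM list contained a run of 5 summits within 2273 bp on chromosome 17, from 39980487 to 39982760, none of them matched. Their scores were between 2.03 and 5.47 and their ranks between 1151 and 1245. A further unmatched DEM summit stood 2744 bp beyond the run, at 39985504 (score 2.68, rank 1237). It made a neighbouring pair with the last summit of the run. Whether this run marks binding is in doubt, since so many weak summits this close together occurred nowhere else in either list, and the region was not checked against repeats or regions of artefactual signal in mm9, which were not used here. Of the 1066 unmatched DEM summits, 30 (2.81%, 95% interval 1.91 to 3.99%) lay within 50 kb of a vehicle summit. They include the DEM summits on chromosomes 6 and 9 that lay 350 and 101 bp from a vehicle summit. No random expectation was computed for this share, so it cannot be called high or low.

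The near-complete inclusion of the vehicle list in the DEM list is the pattern most worth a second look. Coincidence of uniformly random positions is argued against by the 1000 random sets, in which the highest number of matches was 1 against the 180 observed. Summits called once on pooled reads and copied to both lists are argued against too, as 0 percent of the matched summits stood at the identical base. The random sets ignore chromatin state and mappability. Neither test tells shared binding from other signal at the same positions in both libraries. The longer DEM list may reflect a library-wide difference in depth or enrichment, or more binding of the tethered heterodimer after DEM. A matched DEM summit outscored an unmatched one in 96.2% of pairs, which restates the fall of the matched share over the deciles. A library-wide difference predicts this value, but that prediction was written after the matches had been seen and so adds no support. No prediction was written for more binding, which does not forbid this value. Of the 104 DEM summits that scored at or above the median of the shared ones, 90 were matched and 14 were not. The highest-scoring of these 14, on chromosome 6, stood 350 bp from a vehicle summit and was unmatched only by the match distance. These explanations cannot be told apart because depth is unknown and each condition has 1 library.

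The matched share of DEM summits was lowest on chromosome 12, at 1 of 46 (2.17%, 95% interval 0.0550 to 11.5%), and highest on chromosome 18, at 10 of 39 (25.6%, 95% interval 13.0 to 42.1%). A permutation test of the chi-square statistic over 20 chromosomes gave p = 0.198, so a chance spread over chromosomes could account for the difference. The same permutation test within deciles of the DEM score gave p = 0.352. As the test without deciles did not tell the spread from chance, this one cannot decide whether scores that differ between chromosomes play a part.

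It was also tested whether the summits of a shared site stand further apart where scores are weak. The distance had a Spearman's rho of -0.14 with the vehicle score across the 180 sites (permutation p = 0.0613), and of -0.01 with the DEM score (permutation p = 0.860). The median distance was 14.5 bp in the 60 sites with the highest vehicle scores and 20.5 bp in the 60 with the lowest. The prediction had counted a missed threshold as evidence against poorer placement at weak sites, but a missed threshold does not show that distance and score are unrelated, so this stays open.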
